A study of Mus musculus with 18 samples.

How the data were processed

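The study sequenced hippocampal RNA of male mice in 6 groups of 3 libraries, by genotype and treatment. Groups and replicate numbers were taken from the sample titles. RNA extraction with Trizol, doses, training and the interval before tissue was taken are per the labels. The deposited table held TPM values, computed by the authors for RefSeq transcripts. Per the submitters' processing notes, CASAVA was used and the build was hg19, a human build. The aligner and the annotation release are not given in the sources used here. Of the table's start positions 1.75% equalled those of GRCm38.p6, so no build was assigned and positions are as listed.

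The table had 26584 rows for 18690 gene symbols, and 4543 genes had more than 1 row, of which the TPM values were summed; 136 rows repeated an accession and 1481 had no GeneID. Of the GeneIDs 99.9% were in the reference table, each column summed to between 999999 and 1000001 TPM, and 0 symbols were mitochondrial (mt-), so that list could not be tested. Genes with at least 1 TPM in at least 3 of the 18 libraries were tested (14353 genes). Values were analysed as log2(TPM + 1). No counts were used here, so no count model was fitted.

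Linear models were fitted with limma 3.58.1 (R 4.3.3) to all 18 libraries, with 1 mean per group, moderated variances and a trend on the mean level. Comparisons were contrasts of group means, and p-values were adjusted over all genes by the method of Benjamini and Hochberg, with 0.05 as the threshold. There were 13 comparisons: genotype in saline, CSP and CSP-TTK21 against saline in each genotype, TTK21 on CSP in each genotype, treated Het against saline WT, 3 over pooled groups and 2 interactions. Syngap1 over all treatments was tested by exact permutation of genotype within treatment (8000 relabellings). Of 35 gene lists, 33 had at least 5 tested members and were tested with camera, with a preset correlation of 0.01 between genes and with an estimated one. A list's score in a library is the mean deviation of its members from their means over the 18 libraries. Adjusted over the list alone means the adjustment of p-values within the members of a list.

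Genes named in the text followed a rule fixed before the data were examined, as were the groups, comparisons, lists and first set of other settings: Syngap1; per direction, up to 10 genes past the threshold with the largest log2 fold change, whose groups do not overlap and whose mean is at least 1 TPM; where few passed, genes with the smallest p to fill up to 5 per direction; and up to 4 members of each list with the smallest p. Symbols of predicted genes were left out. The gene 9030025P20Rik falls outside the rule and was chosen after its values were seen. Genes with near-identical copies, such as globin and ribosomal protein genes, can share reads, and their values are uncertain.

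Depth was estimated from the table. In each library TPM times transcript length takes values in steps of 1 fragment, and the step gave 3.14 to 9.28 M fragments per library (M, mega). On 9 simulated libraries the largest error of this estimate was 1.01%. The spread of log2 ratios between libraries, for transcripts of at least 40 fragments, was set against counting noise, which simulated Poisson pairs matched at 0.98 to 1.01 times. Transcript lengths were taken from the mouse annotation GENCODE vM21 and covered 98.7% of tested genes, and each library's slope of log2 TPM on log2 length was computed.

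The fit was tested on simulated data, in which 250 genes were changed at each effect size over 5 runs. With 3 against 3 libraries 6.4% of changes of 0.5 on the log2 scale were found, 58% of changes of 1, 90.8% of 1.5 and 98% of 2, with 6.6 false calls per run. With 9 against 9, 56.8% of changes of 0.5 and 94.8% of changes of 1 were found, with 6 against 6, 31.6% and 83.2%, and for an interaction 0.8% and 29.6%. A list moved by -0.3 was called in 20 of 20 runs with the preset correlation and in 19 of 20 with the estimated one, with 1 and 0 calls of other lists. The simulated genes were drawn independently of each other. These runs therefore cannot show how often either test calls lists falsely where genes move together.

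Other settings fixed at that time were a pseudocount of 0.1, no filter, a mean TPM of at least 5, median-ratio scaling, array weights, the replicate number as a block, a fit of the compared groups only, the band of the number that opens each library's description (up to 100, 200 to 400, over 900) as a covariate, and leaving out each library. Added after the data were seen were the length slope as a covariate, averaging each of 2 close pairs of libraries, array weights after that averaging, and a test of transcript rows. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.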

Results

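RNA from the hippocampus of male C57BL/6 mice was sequenced in 6 groups of 3 libraries, wild type (WT) or Syngap1+/- (Het), each given saline, CSP or CSP-TTK21. Syngap1 encodes a Ras GTPase-activating protein of excitatory synapses. CSP is a carbon nanosphere that carries compounds into the brain, and TTK21 is a small molecule that activates the lysine acetyltransferases CBP and p300. Per the labels, mice received 3 doses of 20 mg/kg, 1 per week, were trained for 4 days in the Morris water maze 1 week later and were killed 2 hours after training. The labels describe a dissected dorsal hippocampus in the extraction protocol and the whole hippocampus in the design. Libraries are named by group and replicate number.

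The deposited values were TPM for 18690 gene symbols, of which 14353 were tested. Steps in the low TPM values put the depth at 5.58, 6.29 and 8.84 M fragments (M, mega) in WT saline 1, 2 and 3 and at 6.68, 3.49 and 6.80 M in Het saline. With CSP the depths were 6.04, 9.28 and 5.47 M in WT and 5.62, 3.14 and 6.33 M in Het. With CSP-TTK21 they were 7.70, 3.14 and 6.81 M in WT and 4.12, 5.24 and 5.5 M in Het. No label says whether libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical. Xist was at most 0.03 TPM in every library, and the Y-linked genes Eif2s3y (22.3 to 50.1 TPM) and Ddx3y (14.3 to 27.7 TPM) were present in all 18, as in male tissue.

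Syngap1 (GeneID 240057, listed at positions 27160186 to 27191408 of chromosome 17) did not separate the genotypes. Its level was 81.5 ± 8.13 TPM (SD, n = 3) in WT saline and 56.8 ± 34.1 in Het saline. It was 58.4 ± 6.76 and 59.8 ± 33.7 TPM with CSP, and 60.7 ± 6.10 and 45.05 ± 10.8 TPM with CSP-TTK21, WT before Het. The Het libraries ranged from 24.8 TPM in Het saline 1 to 92.6 TPM in Het saline 2 and 93.4 TPM in Het CSP 2, the highest of all 18. Over the 3 treatments Het minus WT was -0.43 on the log2(TPM + 1) scale, a fold of 0.743, lower in 6 of 9 Het libraries (two-sided exact permutation within treatment, p = 0.117 over 8000 relabellings). Without Het saline 2 the difference was -0.58 (exact permutation p = 0.0345) and without Het CSP 2 -0.56 (0.0182), while without Het saline 1 it was -0.265 (0.218) and without Het CSP 1 -0.262 (0.308). The number that opens each library's description falls in 1 of 3 bands, and only CSP libraries, 4 of 6, were over 900. Band 200 to 400 held Het saline 1, Het CSP 1 and Het CSP-TTK21 2 and 3, the lowest in Syngap1 of all 18, and WT saline 1. With the band, partly mixed with genotype, as a covariate Syngap1 was -0.168 (permutation p = 0.398 after the band's fitted effect was removed).

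The largest trend among the libraries followed transcript length. Each library's slope of log2 TPM, relative to the mean of all libraries, on log2 transcript length ran from -0.189 in Het CSP 1 to 0.205 in Het CSP 2. The first principal component held 26.4% of the variance and correlated with this slope at r = -0.98. Syngap1, a long transcript, moved with the slope over the 18 libraries (r = 0.89, permutation p = 1e-05, the smallest possible, adjusted p = 8e-05 over 8 relations). The rho was 0.79 (permutation p = 0.00025), and r was 0.85 without Het CSP 1 and 2. With the slope as a covariate, an alternative chosen after the data were seen, Syngap1 was -0.33 in Het (permutation p = 0.00375).

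**Figure D1:**
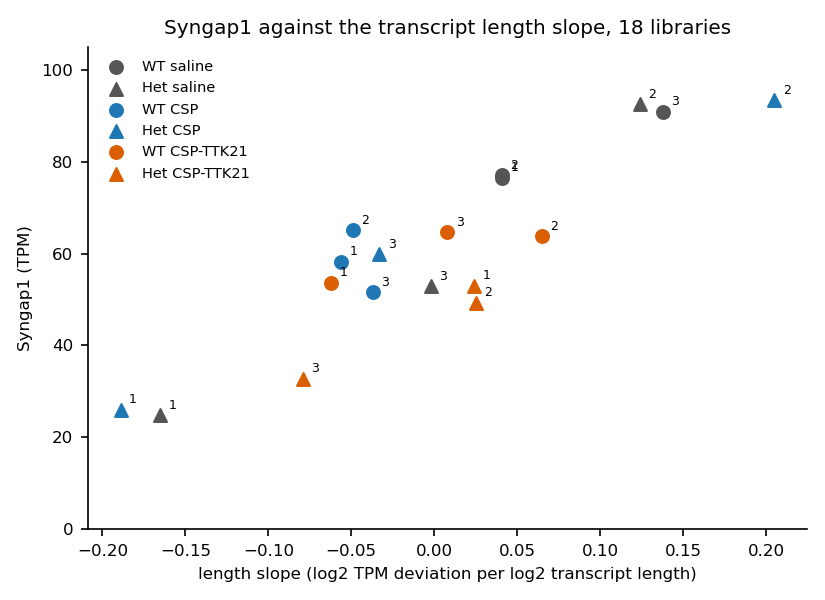
Syngap1 level (TPM, y axis) of each of the 18 libraries against its transcript length slope (x axis, log2 TPM deviation per log2 length), with circles for WT, triangles for Het, colours for treatment and replicate numbers beside the points. Syngap1 lies between 24.8 TPM (Het saline 1, slope -0.165) and 93.4 TPM (Het CSP 2, slope 0.205), and both genotypes span much of that range.

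2 pairs of libraries lay much closer than any other. Het CSP-TTK21 1 and 2 differed by 1.19 times the counting noise and WT saline 1 and 2 by 1.22 times, against 1.53 to 3.79 times in the other 151. Both pairs exceeded counting noise and were kept as separate libraries, but may still be repeats. Then n = 3 overstates their groups, and leaving 1 out keeps its twin. The 4 libraries shared high transthyretin (Ttr), a choroid plexus transcript, at 1734 and 1809 TPM in WT saline and 1481 and 1487 in Het CSP-TTK21. Replicate 3 had 46.5 and 15.1 TPM, and Het CSP 2 the highest, 2137 TPM. Averaging each pair is reported where it ended a call.

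Saline-treated Het mice were first set against saline-treated WT, to see what loss of a Syngap1 copy does. In Het the activity-regulated genes Arc, Egr1, Nr4a1 and Fos, which neurons transcribe within minutes of stimulation, were lower, and so were genes of the myelin sheath. Neuropeptide Y (Npy), a peptide of inhibitory interneurons, and the interferon-stimulated Isg15 were higher. No single gene passed the threshold, whereas 15 of 33 gene lists did with a preset correlation and none with an estimated one.

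Arc was at 66.6 ± 2.95 TPM in WT saline and 28.7 ± 8.08 in Het saline (log2 difference -1.22 ± 0.22 SE), and Egr1 at 87.5 ± 6.72 and 44.4 ± 3.45 (-0.96 ± 0.18). Npy was at 402 ± 10.3 and 1186 ± 453 TPM (1.47 ± 0.23), and Isg15 at 2.80 ± 0.384 and 8.13 ± 1.33 TPM (1.26 ± 0.24), all SD with n = 3. Each of these 4 genes lay on the stated side in 3 of 3 Het libraries without overlap, a separation that chance gives in 10% of 3 against 3 comparisons. Their limma adjusted p over all genes was 0.154, 0.154, 0.0835 and 0.172 in that order. Other genes with the smallest p were Tmsb10, an actin-binding peptide (0.88 ± 0.16), Dynlt1b, a dynein light chain (0.78 ± 0.18), and Tac2, a tachykinin precursor (0.89 ± 0.22), all higher in 3 of 3 Het libraries. Nr4a1 (-1.04 ± 0.23), the protein kinase C gene Prkcd (-1.16 ± 0.26) and the kinase gene Mast3 (-0.63 ± 0.14) were lower in 3 of 3.

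By limma, 0 of 14353 genes passed and 1049 had an unadjusted p under 0.05, 183 higher and 866 lower in Het, where chance gives 718. The median over all tested genes was -0.137, and list tests with camera compare a list with all other genes. Without Het saline 1, 11 genes passed, Npy (1.84), Arc (-1.43), Nr4a1 (-1.38), Tmsb10 (1.01) and the astrocyte filament gene Gfap (1.21) among them, with limma adjusted p of 9.83e-05, 0.0138, 0.00204, 0.0261 and 0.00467. With limma array weights 5646 genes passed, and 3123 did with array weights after each close pair was averaged.

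Immediate early genes fell as a list (camera adjusted p = 0.000171, median -0.44, scores lower in 3 of 3 Het libraries). Of 29 members 23 had negative differences, and 8 lower and 1 higher passed when adjusted over the list alone, Fos (-1.22 ± 0.33) and Nr4a1 among them. The camera adjusted p = 0.195 with an estimated correlation. Oligodendrocyte and myelin genes fell too (camera adjusted p = 1.97e-07, median -0.52, 3 of 3 libraries). All 19 members were negative and 5 passed when adjusted over the list alone, including myelin basic protein Mbp (-0.64 ± 0.21), Mobp (-0.83 ± 0.26), the gap junction gene Gjb1 (-0.84 ± 0.24) and the transcription factor gene Myrf (-0.59 ± 0.18), with camera adjusted p = 0.361 with an estimated correlation. Dentate granule markers fell (camera adjusted p = 0.0106, median -0.26 over 16 members, 3 of 3 libraries), with 2 lower members when adjusted over the list alone, Dsp (-0.98 ± 0.25) and Dock10 (-0.64 ± 0.18), and adjusted p = 0.582 with an estimated correlation.

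Nuclear genes of oxidative phosphorylation rose (camera adjusted p = 3.25e-17, median 0.17, 44 of 50 positive, 3 of 3 libraries), with none passing when adjusted over the list alone and adjusted p = 0.128 with an estimated correlation. Interferon response genes rose (camera adjusted p = 1.89e-06, median 0.14, 19 of 27 positive, 3 of 3 libraries). Isg15 alone passed when adjusted over the list alone, and the list had adjusted p = 0.0933 with an estimated correlation, the lowest of all 429 list tests. The list of inflammation and reactive glia had a median of 0.01 and a mean of 0.21 and passed upward (camera adjusted p = 6.64e-05, 2 of 3 libraries), with adjusted p = 0.361 with an estimated correlation. The galectin gene Lgals3 (1.43 ± 0.36) passed when adjusted over the list alone, and Gfap was at 0.79 ± 0.25.

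These 6 calls held without each of the 6 libraries in turn, and the other 9 did not. Without Het saline 1 the camera adjusted p was 0.174 for the postsynaptic density (median -0.30, Camk2a -0.49 ± 0.16), 0.397 for Ras and ERK signalling (-0.20, Dusp6 -0.53 ± 0.14), 0.778 for intellectual disability and autism genes (-0.26), 0.48 for CA1 pyramidal markers (-0.31, Fibcd1 -0.55 ± 0.16) and 0.48 for cytosolic ribosomal proteins (0.15). It was also 0.676 for voltage-gated channels (-0.21), 0.119 for blood (0.24) and 0.327 for meninges and fibroblasts, a list that passed upward with a median of -0.15 and a mean of -0.04. Without WT saline 3 the camera adjusted p was 0.112 for Ras and ERK signalling, 0.266 for the disability and autism genes, 0.058 for CA1, 0.309 for channels, 0.181 for blood and 0.721 for meninges. Without Het saline 3 it was 0.729 for blood and 0.0654 for channels. The choroid plexus list (-0.96) lost its call without WT saline 1 (camera adjusted p = 0.187) or 2 (0.273) and with the pairs averaged (0.164). Full-data camera adjusted p of these 9 lists, in the order named, were 0.000611, 0.0324, 0.0324, 0.0272, 1.8e-15, 0.0324, 0.0103, 0.032 and 0.00323, against 0.779, 0.875, 0.886, 0.747, 0.361, 0.886, 0.361, 0.498 and 0.779 with an estimated correlation; when adjusted over the list alone only CA1 held passing members, 2 lower. With the length slope as a covariate 6 of the 15 calls held, those of the immediate early, postsynaptic, myelin, oxidative phosphorylation, interferon and inflammation lists.

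**Figure D2:**
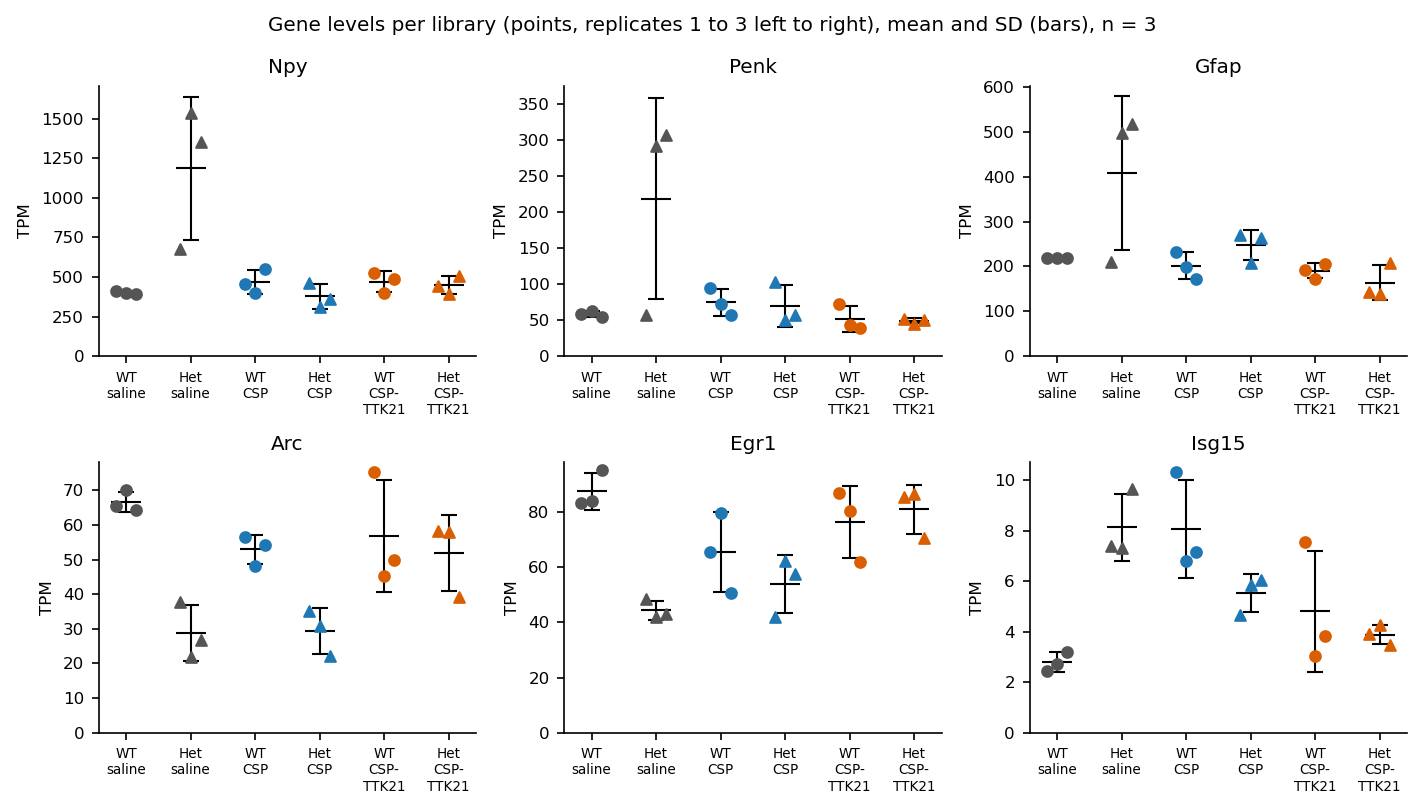
Levels (TPM, y axes starting at 0) of Npy, Penk, Gfap, Arc, Egr1 and Isg15 in the 6 groups, with circles (WT) and triangles (Het) for single libraries and bars for the mean and SD (n = 3). Arc averages 66.6 TPM in WT saline and 28.7 TPM in Het saline, and Npy averages 1186 TPM in Het saline against 377 to 470 TPM in the other 5 groups.

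CSP alone was compared with saline in each genotype, as the control for the carrier. In WT given CSP, the interferon-induced genes Isg15 (1.24 ± 0.24) and Psmb9 (95% interval 0.46 to 2.49) were higher in 3 of 3 libraries, and the lists of choroid plexus, astrocyte and synaptic genes lower. Single genes did not pass, while 12 lists did with the preset correlation and none with an estimated one (lowest adjusted p = 0.622 by camera).

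In WT, 0 genes passed by limma and 855 had p under 0.05 (270 higher, 585 lower; median of all genes -0.11). The smallest adjusted p by limma was 0.506, for the proteasome lid component gene Shfm1 (0.62 ± 0.12) and for Isg15 (1.24 ± 0.24). Both were higher in 3 of 3 libraries without overlap. Rpa3 (0.80 ± 0.17), Pfdn1 (0.51 ± 0.12) and Polr2j (0.59 ± 0.14) followed, and lower were Fam219aos (-0.75 ± 0.15), the syndecan gene Sdc4 (-0.62 ± 0.14), Fam155a (-0.48 ± 0.11), Cdk5rap2 (-0.92 ± 0.22) and Hist1h1c (-1.04 ± 0.25). When only the WT saline and WT CSP libraries were fitted, 207 genes passed (26 higher, 181 lower), and with array weights 672 did.

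Choroid plexus genes fell with CSP in WT (camera adjusted p = 5.28e-08, median -1.16, 21 of 21 negative; adjusted p = 0.622 with an estimated correlation), with Ace (-0.96 ± 0.34) and Cldn2 (-1.23 ± 0.46) as examples. None of the 21 passed when adjusted over the list alone, and the 3 WT CSP libraries were compared with a saline group in which replicates 1 and 2 were high. Postsynaptic genes (camera adjusted p = 0.000127, median -0.28), presynaptic genes (0.00285, -0.27), intellectual disability and autism genes (4.45e-05, -0.29; Ube3a -1.0 ± 0.34, Grin2b -0.83 ± 0.30) and voltage-gated channels (0.00261, -0.26) fell in 3 of 3 libraries, with none passing when adjusted over the list alone and adjusted p = 0.728 with an estimated correlation for each of the 4. With the length slope as a covariate these 4 lost their calls, at camera adjusted p of 0.12, 0.342, 0.278 and 0.671. Oxidative phosphorylation (camera adjusted p = 8.25e-09, median 0.12) and ribosomal proteins (4.04e-10, 0.19) rose and also lost their calls with the length covariate (0.671 and 0.609). Uqcrb (0.54 ± 0.14) and Atp5j (0.57 ± 0.15) passed when adjusted over the list alone, and the 2 lists had adjusted p = 0.622 and 0.638 with an estimated correlation. Heat shock and unfolded protein response genes rose (camera adjusted p = 0.000127, median 0.07, 3 of 3 libraries), none when adjusted over the list alone (Hspe1 0.42 ± 0.14, Xbp1 0.47 ± 0.16), with adjusted p = 0.622 with an estimated correlation.

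Astrocyte genes fell in WT given CSP (camera adjusted p = 0.0317, median -0.17), with Gja1 (-0.52 ± 0.15) and Slc1a2 (-0.53 ± 0.16), the main astrocytic connexin and glutamate transporter, passing when adjusted over the list alone; the call was lost without WT saline 1 (0.0692) or 2 (0.0542) or WT CSP 2 (0.0734) or 3 (0.172), and with the pairs averaged (0.0581). Immediate early genes (camera adjusted p = 0.0317, median -0.22, none when adjusted over the list alone; Sik1 -0.61 ± 0.23) lost theirs without WT saline 1 (0.0964) or 2 (0.0533) or WT CSP 3 (0.134), and with the pairs averaged (0.0612). The interferon list (camera adjusted p = 0.012, median 0.03, 2 of 3 libraries) had Isg15 passing when adjusted over the list alone and lost its call without WT saline 3 (0.21) or WT CSP 1 (0.124) or 2 (0.0734). Blood genes (camera adjusted p = 0.0317, median 0.35), whose near-identical globin copies can share reads, lost theirs without WT saline 3 (0.227) or WT CSP 2 (0.152). All 4 had adjusted p = 0.622 with an estimated correlation. The length covariate ended the interferon (0.772) and blood (0.671) calls, and the description band those of immediate early (0.183) and blood genes (0.104) and of astrocytes (0.80, with the opposite direction).

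In Het given CSP, Npy fell by 1.58 on the log2 scale, from 1186 ± 453 to 377 ± 76.6 TPM (SD, n = 3), lower in 3 of 3 libraries. It was the only gene to pass in any comparison of 2 single groups, at a limma adjusted p of 0.0334, and its level in Het CSP was close to that in WT saline (402 ± 10.3 TPM). Without Het saline 2 the difference was -1.36 (limma adjusted p = 0.19), without Het saline 3 -1.45 (0.464), without Het CSP 2 -1.46 (0.126) and without Het CSP 3 -1.56 (0.307), each with 0 genes passing, and without Het saline 1 14 genes passed, Rgs4 (-1.07, limma adjusted p = 0.0183) among them. The limma adjusted p was 0.0633 with the pairs averaged, 0.0896 with the length covariate, 0.061 with the replicate block, 0.999 with the description band, 0.0892 with median-ratio scaling, 0.155 with no filter and 1 with only these groups fitted.

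In all, 747 genes had p under 0.05 (442 higher, 305 lower). Among those with the smallest p, Mroh7 (1.02 ± 0.22), the spermine oxidase gene Smox (0.58 ± 0.14), Rab42 (1.44 ± 0.35), Ovgp1 (1.13 ± 0.28) and Ssbp4 (0.76 ± 0.19) were higher. Lower were the G protein regulator gene Rgs4 (-0.82 ± 0.19), the cholesterol synthesis gene Hmgcs1 (-0.73 ± 0.17), S100a4 (-1.53 ± 0.37) and Lst1 (-1.03 ± 0.26). All were without overlap and none past the threshold. With array weights 8271 genes passed, 7906 after the pairs were averaged.

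The 5 lists that passed in Het given CSP were dentate granule (median 0.27) and endothelium and pericytes (0.22), which rose, and adult neurogenesis (-0.09), oxidative phosphorylation (-0.07) and interferon response (-0.16), which fell. Their camera adjusted p was 0.016, 0.016, 0.0388, 0.016 and 0.016 in that order, each had adjusted p = 0.99 with an estimated correlation, and no member passed when adjusted over the list alone. Cldn5, the tight junction protein of brain endothelium, was at 0.66 ± 0.18, the new-neuron gene Igfbpl1 at -1.16 ± 0.33, and the interferon-induced Ifit3 and Xaf1 at -0.79 ± 0.25 and -1.08 ± 0.34. None of the 5 held when each library was left out, nor with the length covariate. Without Het saline 1 the camera adjusted p was 0.0612, 0.0612, 0.936 and 0.641 for the dentate, endothelial, oxidative and interferon lists, and without Het saline 3 it was 0.0594, 0.0594, 0.17 and 0.071. Without Het CSP 2 it was 0.295, 0.0502 with the opposite direction, and 0.434 for the dentate, oxidative and interferon lists, and without Het CSP 3 it was 0.351 for endothelium. Adult neurogenesis lost its call without Het saline 2 (0.0809) or 3 (0.172) or Het CSP 1 (0.0765) or 3 (0.351). With the description band the camera adjusted p was 0.432, 0.121, 0.881 and 0.765 for endothelium, neurogenesis, oxidative phosphorylation and interferon response.

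TTK21 was read from CSP-TTK21 against CSP, both at 20 mg/kg. As only CSP libraries (4 of 6) were in the band over 900, TTK21 and band are partly mixed. In WT no gene and 1 list passed. Intellectual disability and autism genes passed alone (camera adjusted p = 0.0321, median 0.10, 32 of 34 positive, 2 of 3 libraries, none when adjusted over the list alone; adjusted p = 0.985 with an estimated correlation), with Grin2b at 0.56 ± 0.30 and Ube3a at 0.58 ± 0.34. That call was lost without WT CSP 1 (0.0664) or 3 (0.0548) or WT CSP-TTK21 2 (0.302), and with the length covariate (0.341).

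No WT gene passed by limma (0 calls), 282 had p under 0.05 and the smallest adjusted p was 1. The small nucleolar host gene Snhg1 (-0.72, 95% interval -1.09 to -0.36), the ATPase gene Tor1a (-0.44 ± 0.12) and the scaffold gene Lrrc1 (-0.91 ± 0.25) were lower and the lipid droplet gene Pnpla3 (0.85 ± 0.26) higher in 3 of 3 libraries. For the median gene the 95% interval reached 0.46 on the log2 scale to either side, so smaller differences were left open. Egr1 was at 0.23 with an interval of -0.14 to 0.60.

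In Het, TTK21 on CSP went with higher myelin genes and higher Arc and Egr1, and with lower endothelial genes. The myelin protein gene Plp1 was at 1.18 ± 0.34, and Opalin, a marker of mature oligodendrocytes, at 1.35 ± 0.38. Arc was at 0.80 (95% interval 0.34 to 1.27), from 29.4 ± 6.63 to 51.8 ± 10.96 TPM, and Egr1 at 0.59 (0.22 to 0.96), from 54.0 ± 10.6 to 81.0 ± 8.90 TPM (SD, n = 3), both in 3 of 3 libraries. No single gene passed over all genes, and 9 lists did with the preset correlation and none with an estimated one.

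With limma 0 genes passed, 617 had p under 0.05 (334 higher, 283 lower) and the smallest adjusted p was 0.536. It belonged to Cacng6, a calcium channel gamma subunit gene (1.99 ± 0.39), and Klhl36, a ubiquitin ligase adaptor gene (-1.01 ± 0.20). Adamtsl2 (0.98 ± 0.24), Morn5 (1.80 ± 0.46), Cbfa2t3 (0.86 ± 0.22) and Jam3 (0.55 ± 0.14) were also higher. Sergef (-0.74 ± 0.16), Snhg20 (-0.92 ± 0.20), Zfp951 (-1.19 ± 0.27) and Zfp777 (-0.73 ± 0.17) were lower. All held in 3 of 3 libraries without overlap. Without Het CSP-TTK21 3, 3 genes passed, Snhg20 among them (-1.20, limma adjusted p = 0.0166). With array weights 4510 genes passed, and 624 did after the pairs were averaged.

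Myelin genes rose (camera adjusted p = 5.9e-16, median 0.54, 19 of 19 positive, 3 of 3 libraries), and 9 passed when adjusted over the list alone, Opalin, Plp1, Cldn11 (0.66 ± 0.22) and Ugt8a (1.08 ± 0.36) among them, with adjusted p = 0.265 with an estimated correlation. Endothelial and pericyte genes fell (camera adjusted p = 9.34e-06, median -0.28, 21 of 24 negative, 3 of 3 libraries, none when adjusted over the list alone; adjusted p = 0.265 with an estimated correlation), with von Willebrand factor Vwf at -1.03 ± 0.32 and Ly6a at -0.80 ± 0.32. Heat shock and unfolded protein response genes rose (camera adjusted p = 1.33e-05, median 0.24, 23 of 28 positive, 3 of 3 libraries, none when adjusted over the list alone; adjusted p = 0.38 with an estimated correlation), with Manf at 0.35 ± 0.14 and Hspd1 at 0.30 ± 0.14. These 3 calls held without each library in turn.

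Glucocorticoid response (camera adjusted p = 1.45e-05, median -0.40; Mt2 -0.75 ± 0.29, Fkbp5 -0.57 ± 0.25) and inflammation and reactive glia (camera adjusted p = 3.82e-05, median -0.47; Icam1 -1.22 ± 0.48, Socs3 -1.09 ± 0.45, Gfap -0.61 ± 0.25) fell, and both calls came from Het CSP 3. Its scores on the 2 lists were 1.12 and 1.24, where the next highest of the 18 libraries had 0.205 and 0.41, and without it the camera adjusted p was 0.918, with the opposite direction, and 0.812. Its myelin score was also the lowest, at -0.828, and without it the myelin call held (camera adjusted p of at most 3.73e-08 without any library). Astrocyte genes (camera adjusted p = 0.00174, median -0.13) lost their call without Het CSP 1 (0.45). Immediate early genes (camera adjusted p = 0.0226, median 0.16) lost theirs without Het CSP 1 (0.0833) or 2 (0.437) or Het CSP-TTK21 1 (0.0943), and ependyma (camera adjusted p = 0.00234, median 0.40, Pifo 1.36 ± 0.50) without Het CSP 1 (0.0702) or Het CSP-TTK21 1 (0.0902) or 2 (0.123). With the pairs averaged these 2 had camera adjusted p = 0.0564, and with the description band 0.0538 and 0.0663. The band also ended the glucocorticoid (0.0873) and precursor (0.587) calls. Oligodendrocyte precursor genes (camera adjusted p = 0.0416, median 0.18) lost theirs without Het CSP 2 (0.126) or 3 (0.432) or Het CSP-TTK21 1 (0.0902) or 3 (0.146), and with the length covariate (0.0891). In these 6 lists Enpp6 alone, a gene of newly formed oligodendrocytes (0.94 ± 0.25), passed when adjusted over the list alone, and the 6 had adjusted p = 0.38, 0.38, 0.265, 0.38, 0.38 and 0.458 with an estimated correlation, in the order named.

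**Figure D3:**
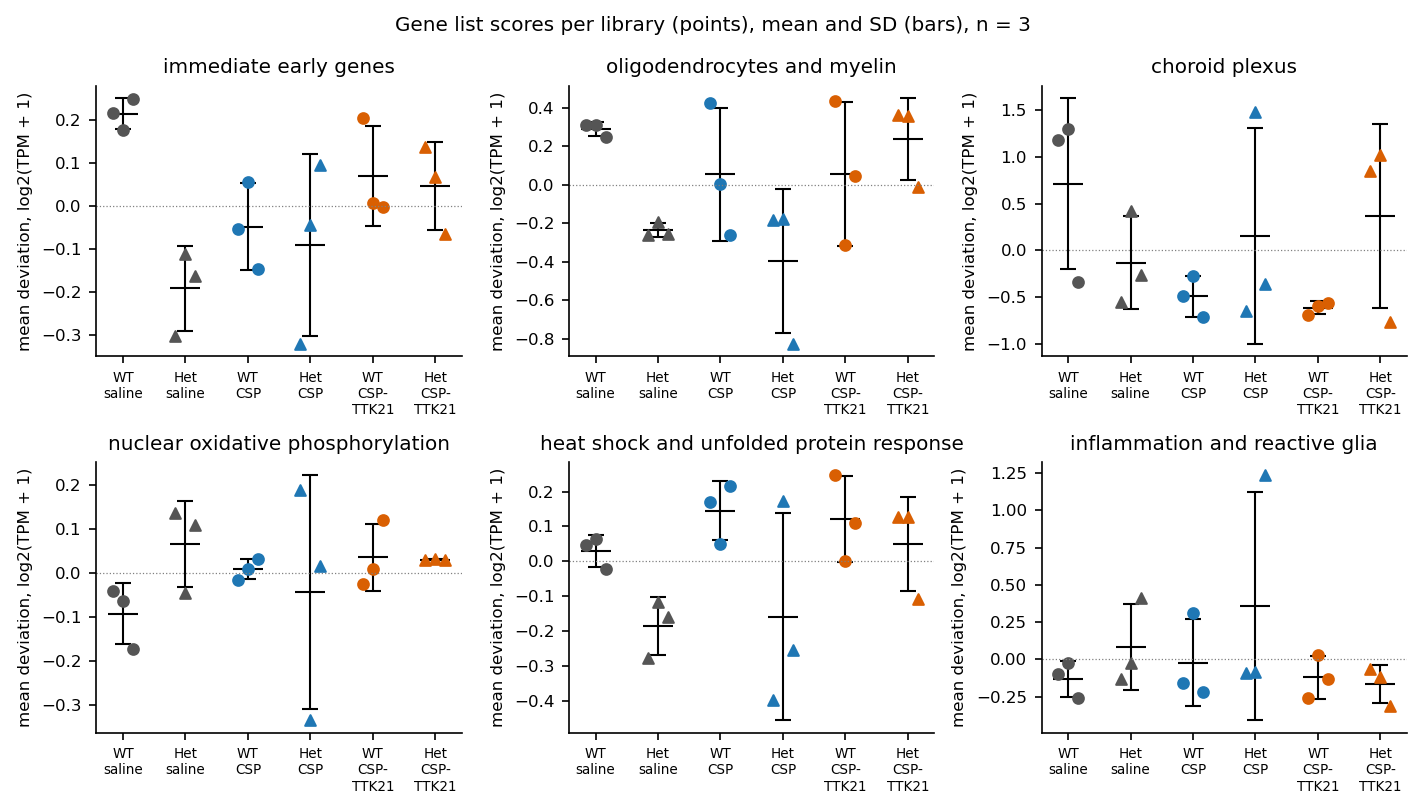
Gene list scores (y axes, mean deviation of the members' log2(TPM + 1) from their mean over 18 libraries) of 6 lists by group, with points for libraries and bars for the mean and SD (n = 3). Het CSP 3 has the highest inflammation score (1.24) and the lowest myelin score (-0.828), and the choroid plexus score is above 0.8 in 5 libraries of 3 groups.

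CSP-TTK21 was also set against saline. In WT, 7 lists passed with the preset correlation and none with an estimated one (adjusted p of 0.286 to 0.859), the choroid plexus, astrocyte, dentate granule and postsynaptic lists downward and those of oxidative phosphorylation, ribosomal proteins and heat shock upward. The choroid plexus score was 1.18 and 1.30 in WT saline 1 and 2 but -0.336 in WT saline 3, against -0.556 to -0.687 in the treated libraries. Folr1, the folate receptor of the choroid plexus, was at -2.55 ± 0.79 and the astrocyte transcription factor gene Sox9 at -0.47 ± 0.17, while Ndufs6, a complex I subunit gene, was at 0.38 ± 0.14. By limma 0 genes passed, 353 had p under 0.05 (95 higher, 258 lower; median of all genes -0.108) and the smallest adjusted p was 0.963. Shfm1 (0.46 ± 0.12) and Rpa3 (0.65 ± 0.17), also among the first with CSP alone against the same saline libraries, were higher, and Slc24a5 (-1.06 ± 0.29), Pcdhgb4 (-1.07 ± 0.29) and Lgals3bp (-0.63 ± 0.19) lower.

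The camera adjusted p in WT was 3.49e-13 for choroid plexus (median -1.24, 20 of 21 negative; Kcnj13 -1.89 ± 0.68), 1.4e-16 for oxidative phosphorylation (0.14), 6.6e-15 for ribosomal proteins (0.13), 2.47e-05 for heat shock (0.06, Atf4 0.29 ± 0.13, 2 of 3 libraries) and 0.00541 for astrocytes (-0.19, 17 of 18 negative). With an estimated correlation the adjusted p was 0.544, 0.286, 0.658, 0.658 and 0.544, and no member of any passed when adjusted over the list alone. Postsynaptic genes (camera adjusted p = 0.00141, median -0.22, 33 of 33 negative; Camk2a -0.42 ± 0.16) and dentate granule genes (camera adjusted p = 0.00541, median -0.27; Dock10 -0.52 ± 0.18) lost their calls without WT CSP-TTK21 1 (0.0696 and 0.106), had none passing when adjusted over the list alone, and had adjusted p = 0.859 and 0.747 with an estimated correlation. The length covariate ended the postsynaptic (0.0955) and ribosomal (0.054) calls, and the description band the astrocyte call (0.131).

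In Het, CSP-TTK21 against saline went with higher immediate early and myelin lists (adjusted p = 0.463 for both with an estimated correlation) and lower Npy and Gfap. Arc rose within its list by 0.84 ± 0.22, from 28.7 ± 8.08 to 51.8 ± 10.96 TPM, with Egr1 (0.85 ± 0.18), Npas4 (1.16 ± 0.29) and Nr4a1 (0.84 ± 0.23), transcription factor genes induced by neuronal activity. Gfap (-1.23 ± 0.25) and Lgals3 (-1.31 ± 0.36), genes of reactive glia, and Isg15 (-0.89 ± 0.24) fell within their lists. Npy (-1.32 ± 0.23) and the enkephalin precursor gene Penk (-1.79 ± 0.45) were lower in 3 of 3 libraries but not past the threshold over all genes. Penk and Gfap were high in Het saline 2 and 3, while Het saline 1 (57.4 and 210 TPM) was near the treated libraries.

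The limma test called 0 genes, 670 had p under 0.05 (421 higher, 249 lower) and the smallest adjusted p was 0.193, for Npy and Cacng6 (2.18 ± 0.39). Galnt9 (0.58 ± 0.13), Stc1 (1.01 ± 0.24) and the neurotrophin gene Ntf3 (1.40 ± 0.34) were also higher. Krt1 (-0.90 ± 0.22) and Rnase1 (-1.44 ± 0.36) were lower. All held in 3 of 3 libraries without overlap. Without Het saline 1, 17 genes passed, Penk (-2.58), Gfap (-1.65) and Npy (-1.69) among them, each at a limma adjusted p of 0.000146, and without Het CSP-TTK21 3, 1 did. With array weights 3672 genes passed, and 153 did after the pairs were averaged.

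Immediate early genes rose (camera adjusted p = 0.00231, median 0.28, 20 of 29 positive, 3 of 3 libraries), with 5 passing when adjusted over the list alone and adjusted p = 0.463 with an estimated correlation. Myelin genes rose (camera adjusted p = 5.34e-10, median 0.47, 19 of 19 positive, 3 of 3 libraries, none when adjusted over the list alone; adjusted p = 0.463 with an estimated correlation; Cldn11 0.64 ± 0.22). Heat shock and unfolded protein response genes rose (camera adjusted p = 2.77e-05, median 0.22, 25 of 28 positive, 3 of 3 libraries, none when adjusted over the list alone; adjusted p = 0.714 with an estimated correlation; Hspa5 0.48 ± 0.21). These 3 calls held without each library. The interferon list fell (camera adjusted p = 0.000157, median -0.16, 1 lower when adjusted over the list alone; adjusted p = 0.284 with an estimated correlation) but not without Het saline 1 (0.25). The inflammation list fell (camera adjusted p = 0.00973, median -0.14, 2 lower when adjusted over the list alone; adjusted p = 0.857 with an estimated correlation) but not without Het saline 1 (0.0664) or 3 (0.277), nor with the length covariate (0.084). Choroid plexus genes rose (camera adjusted p = 0.0255, median 0.54, 2 of 3 libraries, none when adjusted over the list alone; adjusted p = 0.88 with an estimated correlation) but not without Het saline 1 (0.128) or Het CSP-TTK21 1 (0.337) or 2 (0.644), nor with the pairs averaged (0.439) or the length covariate (0.0758).

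**Figure D4:**
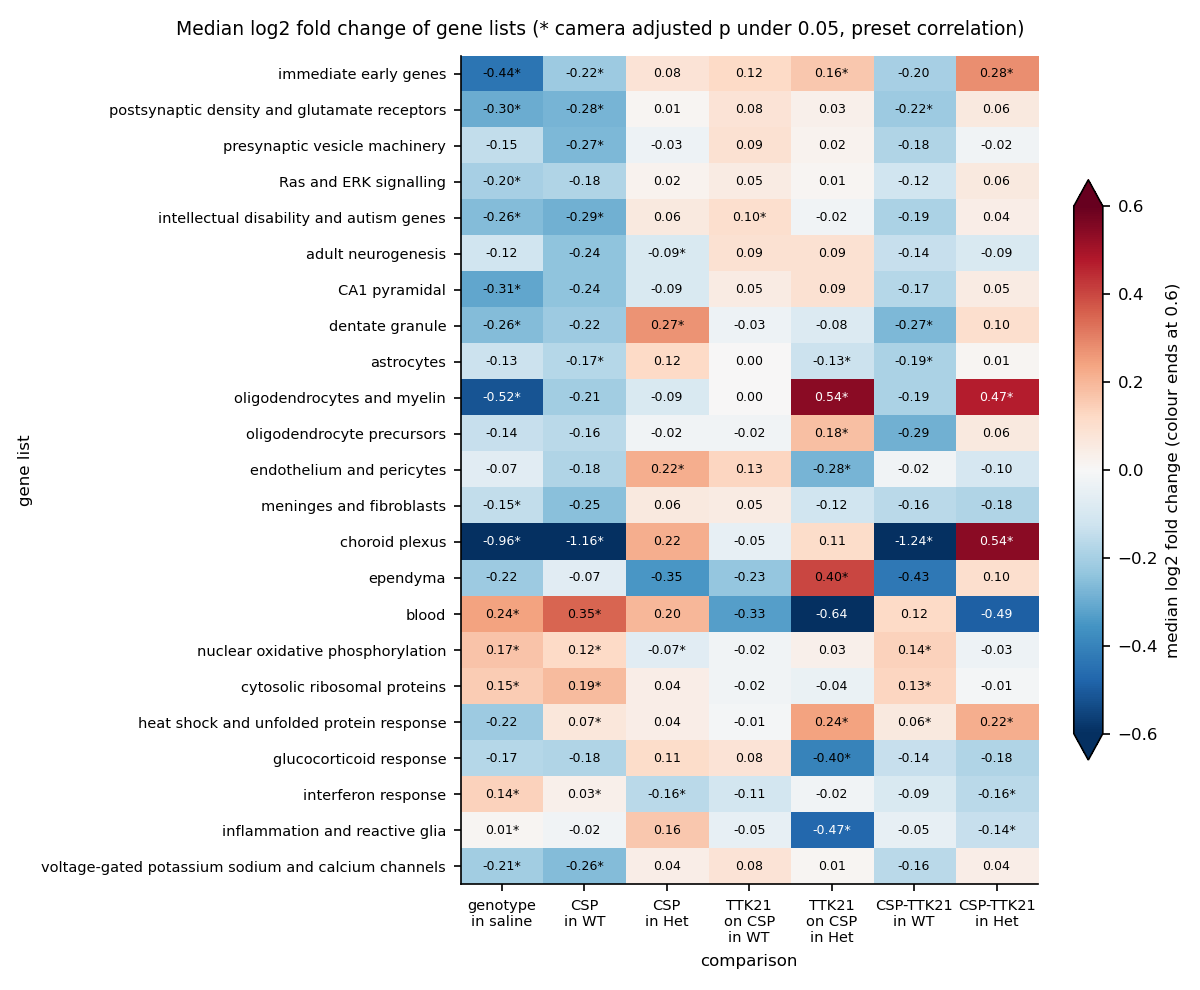
Median log2 fold change (colour and printed value) of the gene lists (rows) that passed in at least 1 of 7 comparisons between single groups (columns), with a star where the camera adjusted p is under 0.05 with the preset correlation. Myelin genes have medians of -0.52 for genotype in saline, 0.54 for TTK21 on CSP in Het and 0.47 for CSP-TTK21 in Het.

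Treated Het mice were next set against saline-treated WT. Genes of oxidative phosphorylation (camera adjusted p = 7.57e-12, median 0.13, 42 of 50 positive) and ribosomal proteins (camera adjusted p = 4.69e-15, median 0.14, 58 of 61 positive) were higher, and glucocorticoid-responsive genes (camera adjusted p = 0.0201, median -0.43, 17 of 21 negative; Arl4d -0.91 ± 0.28, Mertk -0.80 ± 0.30) lower, each in 3 of 3 libraries. With an estimated correlation the adjusted p was 0.749, 0.895 and 0.895, and 1 ribosomal gene passed when adjusted over the list alone, Rps27 (4.06 ± 0.88), whose near-identical copies can share reads. The glucocorticoid call was lost without Het CSP-TTK21 3 (0.191) and the ribosomal call with the length covariate (0.0632).

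Against saline WT limma called 0 genes, 621 had p under 0.05 (162 higher, 459 lower) and the smallest adjusted p was 0.878. Cacng6 (1.61 ± 0.39), the GTPase-activating protein gene Tagap (1.59 ± 0.40) and Ikbip (0.65 ± 0.18) were higher and the extracellular superoxide dismutase gene Sod3 (-1.14 ± 0.25), Zfp951 (-1.09 ± 0.27), Dpf3 (-1.42 ± 0.38) and Rsph3a (-0.74 ± 0.20) lower, and Syngap1 was at -0.87 ± 0.39. Fitting the 2 groups alone gave 4 genes, array weights 264, and leaving out Het CSP-TTK21 3 gave 1, the splicing factor gene Cwc22 (3.07, limma adjusted p = 0.000132).

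Genes of chromosome 17 led the comparison of genotype over all 3 treatments, 9 libraries against 9. Dynlt1b, a dynein light chain gene, was at 99.9 ± 22.7 TPM in Het and 59.7 ± 10.8 in WT (SD, n = 9; 0.72 ± 0.10, limma adjusted p = 0.0102), on its side in 9 of 9 libraries. Rsph3a, which encodes a radial spoke protein of cilia, was at 18.3 ± 4.88 and 29.6 ± 3.38 TPM (-0.70 ± 0.11, limma adjusted p = 0.0428, 8 of 9 libraries). The third gene to pass was the uncharacterised 9030025P20Rik (0.79 ± 0.10, limma adjusted p = 0.00613, 9 of 9 libraries), named after its values were seen.

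These 3 genes start at positions 6697511, 8164446 and 15199078 of chromosome 17, and Syngap1 at 27160186 in the same coordinates. Gnptg, at 25451324, separated the genotypes without overlap at 91.3 ± 9.21 TPM in WT and 69.5 ± 4.18 in Het (-0.38 ± 0.07, limma adjusted p = 0.0597). Tagap (1.24 ± 0.23, limma adjusted p = 0.0938) and Unkl (-0.41 ± 0.09, 0.275) lie on the same chromosome and were on their side in 9 of 9 libraries. Arc was lower in 7 of 9 Het libraries (-0.73 ± 0.13, limma adjusted p = 0.0623). Outside these, Dnaic1 (0.66 ± 0.15), Sbsn (0.87 ± 0.20) and Phf7 (0.46 ± 0.11) were higher and Cystm1 (-0.43 ± 0.09) lower.

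With each close pair averaged none of the 3 genes passed, at limma adjusted p of 0.0596 for 9030025P20Rik, 0.0919 for Dynlt1b and 0.289 for Rsph3a. Rsph3a lost its call without any of 15 libraries (limma adjusted p of at most 0.155, without WT CSP 1). Without Het CSP 1 and without Het CSP 2, 7 and 11 genes passed, including Gnptg (0.0478 and 0.0317) and Arc (0.0354 and 0.0456), all 3 genes above among them. With the length covariate 9 passed, including Gnptg (0.0144), Unkl (0.0219) and Arc (0.0219), and with a mean TPM of at least 5, 5 did. In all, 930 genes had p under 0.05 (234 higher, 696 lower), and array weights gave 3192 (1218 with the pairs averaged).

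Over all treatments myelin genes were lower in Het (camera adjusted p = 2.13e-06, median -0.27, 19 of 19 negative, 7 of 9 libraries; Mag -0.37 ± 0.12, Mal -0.48 ± 0.17). Heat shock and unfolded protein response genes were lower (camera adjusted p = 1.39e-06, median -0.21, 26 of 28 negative, 6 of 9 libraries; Pdia4 -0.37 ± 0.11), and meninges and fibroblast genes higher (camera adjusted p = 0.000122, median 0.19, 6 of 9 libraries; Foxd1 0.44 ± 0.16). No member of the 3 lists passed when adjusted over the list alone, each had adjusted p = 0.492 with an estimated correlation, and the calls held without each library. Immediate early genes were lower (camera adjusted p = 0.00578, median -0.16, 6 of 9 libraries; adjusted p = 0.492 with an estimated correlation), with Arc and Egr1 (-0.38 ± 0.10) passing when adjusted over the list alone, but not without Het CSP 2 (0.0979).

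The other 7 lists passed upward in Het by camera against all genes (median -0.054) and lost the call without 1 or more libraries. They were inflammation (adjusted p = 2.01e-05, median 0.15; 0.0565 without Het CSP 3), ribosomal proteins (1.96e-08, 0.07; 0.108 without Het saline 1), oxidative phosphorylation (0.000251, 0.03; 0.097 without Het saline 1, 0.449 without Het CSP 1) and choroid plexus (0.000365, 0.15; 0.253 without WT saline 3, 0.083 without Het CSP 2). Astrocytes (camera adjusted p = 0.0284, median 0.00, mean 0.05) lost it without WT saline 3 (0.0563), Het saline 1 (0.125), WT CSP 3 (0.102), Het CSP 1 (0.237) or Het CSP-TTK21 3 (0.109). Adult neurogenesis (camera adjusted p = 0.0485, median 0.03; Sox11 0.45 ± 0.13, passing when adjusted over the list alone) and interferon response (0.0482, 0.01) lost it without any of 11 and of 9 libraries. Their adjusted p with an estimated correlation was 0.492, 0.629, 0.629, 0.834, 0.492, 0.835 and 0.492 in the order named. Scores were higher in 7 of 9 Het libraries (ribosomal), 4 (choroid plexus) or 5 (others). Averaging the pairs ended the neurogenesis call (0.0995), the length covariate those of neurogenesis (0.0515), astrocytes (0.0687) and interferon (0.241), and the description band those of astrocytes (0.442), oxidative phosphorylation (0.732), ribosomal proteins (0.892) and interferon (0.593).

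**Figure D5:**
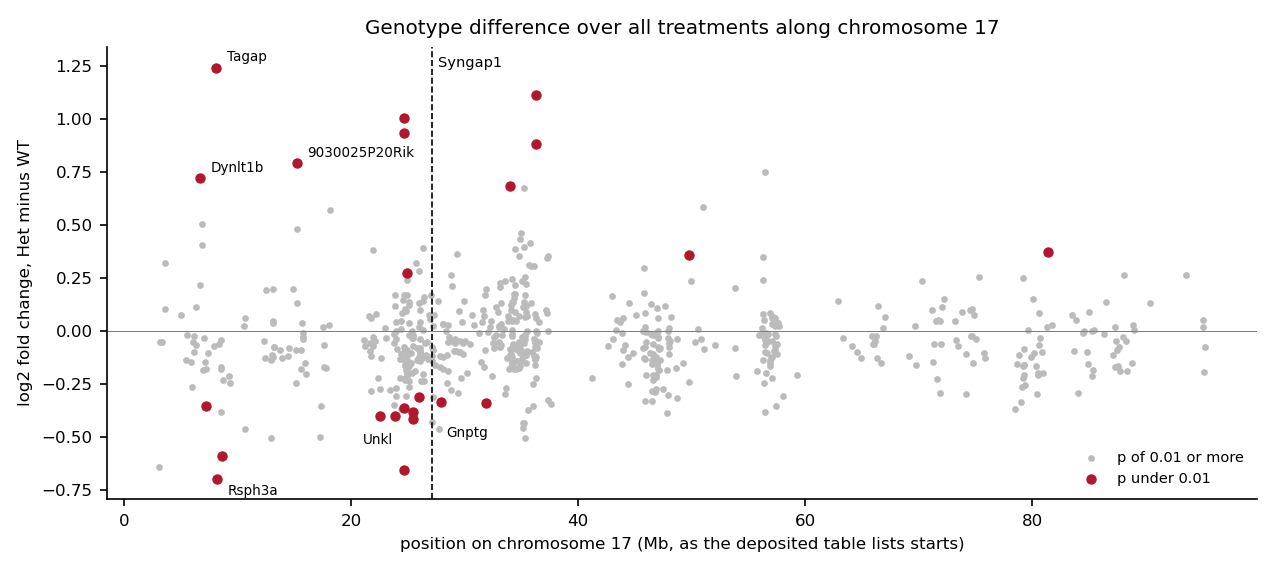
Log2 fold change of Het minus WT over all treatments (y axis) of tested genes along chromosome 17 (x axis, Mb, as listed in the deposited table), with red points for an unadjusted p under 0.01 and a dashed line at Syngap1. Dynlt1b (0.72), Tagap (1.24), Rsph3a (-0.70) and 9030025P20Rik (0.79) lie between 6.70 and 15.2 Mb, and Gnptg and Unkl close to Syngap1.

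TTK21 on CSP was pooled over both genotypes, 6 libraries against 6. Myelin genes were higher (camera adjusted p = 7.4e-10, median 0.30, 18 of 19 positive, 4 of 6 libraries). The median was 0.54 in Het and 0.00 in WT (10 of 19 positive). None passed when adjusted over the list alone (adjusted p = 0.466 with an estimated correlation). Plp1 was at 0.66 ± 0.24 and Opalin at 0.68 ± 0.27. The call held without each library, but with the description band the list had the opposite direction (camera adjusted p = 0.29) and Opalin was at -0.14. Immediate early genes rose in 6 of 6 libraries (camera adjusted p = 0.00555, median 0.12, none when adjusted over the list alone; adjusted p = 0.466 with an estimated correlation), but not without Het CSP 2 (0.114) or with the band (0.0649). Egr2 was at 0.72 ± 0.21 and Egr1 at 0.41 ± 0.12. Across the 12 libraries limma called 0 genes, 416 had p under 0.05 (179 higher, 237 lower), array weights gave 1784 (70 with the pairs averaged) and leaving out Het CSP-TTK21 3 gave 3. Klhl36 (-0.59 ± 0.14) and Zfp647 (-0.56 ± 0.15) separated the groups without overlap, and Snhg1 (-0.49 ± 0.12), Snhg20 (-0.60 ± 0.14) and Fam181a (-0.87 ± 0.23) were lower and Cbfa2t3 (0.58 ± 0.16) and Trim59 (0.50 ± 0.15) higher in 6 of 6 libraries.

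The other 9 lists of that comparison lost their camera calls without at least 1 library. Inflammation (adjusted p = 0.000415, median -0.33) lost it without Het CSP 3 (0.388), cortex (0.0169, 0.13) without Het CSP 1 (0.078), and glucocorticoid response (0.0169, -0.14) without Het CSP 3 (0.45, with the opposite direction) or Het CSP-TTK21 3 (0.156). Heat shock (0.00836, 0.12) lost its camera call without WT CSP 2 (0.0713), Het CSP 3 (0.105) or WT CSP-TTK21 1 (0.0896), blood (0.0169, -0.47) without WT CSP 2 (0.0512), Het CSP 1 (0.0518) or 3 (0.188), and astrocytes (0.0224, -0.08) without WT CSP 1 (0.155), Het CSP 1 (0.501) or Het CSP-TTK21 1 (0.0775). Interferon response (camera adjusted p = 0.0311), with a median of 0.00 and a mean of -0.11, dentate granule (0.0488, -0.11) and endothelium (0.0406, -0.10) lost it without any of 6, 5 and 7 libraries. With an estimated correlation the adjusted p was 0.466 for inflammation, blood, astrocytes and interferon, 0.658 for cortex and 0.756 for the other 4, and no member of the 9 passed when adjusted over the list alone. Averaging the pairs ended the astrocyte call (0.0587), and the length covariate those of astrocytes (0.132), endothelium (0.20), blood (0.198), glucocorticoid (0.0674) and interferon response (0.289). The description band ended those of endothelium (0.819), blood (0.0972), inflammation (0.0722) and glucocorticoid response (0.575, with the opposite direction).

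CSP against saline over both genotypes called 7 lists, each with adjusted p = 0.929 with an estimated correlation and with no member passing when adjusted over the list alone. Ribosomal proteins (camera adjusted p = 3.22e-06, median 0.10) and heat shock genes (0.0154, 0.08; Xbp1 0.30 ± 0.12) rose, and presynaptic genes (0.0153, -0.16), choroid plexus (0.0153, -0.46; Calml4 -0.84 ± 0.35), adult neurogenesis (0.0154, -0.17; Sox11 -0.44 ± 0.15), myelin (0.0415, -0.17) and disability and autism genes (0.0488, -0.10) fell. With the description band the myelin list passed in the opposite direction (0.00281), and heat shock (0.194) and neurogenesis (0.104) did not pass. Averaging the pairs ended the myelin (0.0778) and choroid plexus (0.144) calls, and the length covariate those of presynaptic genes (0.0688), neurogenesis (0.0688), choroid plexus (0.12), ribosomal proteins (0.744) and disability and autism genes (0.744). None of the 7 held without each library. The ribosomal list lost its camera call without Het saline 2 (0.882) or Het CSP 1 (0.253) and neurogenesis without Het CSP 3 (0.141). The highest camera adjusted p without 1 library was 0.625 for heat shock (Het CSP 2), 0.197 for presynaptic genes (Het saline 2), 0.241 for choroid plexus (WT saline 2), 0.501 for myelin (Het CSP 3) and 0.491 for disability and autism genes (Het CSP 1).

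Here limma called 0 genes, 681 had p under 0.05 (293 higher, 388 lower), and array weights gave 5175 (4007 with the pairs averaged). Galnt9 (0.40 ± 0.09), Tjap1 (0.58 ± 0.14) and Dusp28 (0.42 ± 0.11) were higher and Hmgcs1 (-0.52 ± 0.12), Enpp6 (-0.68 ± 0.18), Rgs4 (-0.50 ± 0.13) and Sox3 (-0.61 ± 0.17) lower in 6 of 6 libraries. Npy (-0.69 ± 0.16) was lower in 4 of 6, and without Het saline 1 it passed (-0.87, limma adjusted p = 0.0119) with 1 other gene.

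Interaction terms tested whether treatments acted differently in the 2 genotypes. For CSP, Npy (-1.79 ± 0.33), Isg15 (-1.72 ± 0.34), Shfm1 (-0.79 ± 0.17) and Tmsb10 (-1.06 ± 0.23) had the smallest p on the lower side and Epas1, a hypoxia-inducible factor gene (1.14 ± 0.23), Zcchc24 (0.82 ± 0.19) and Tob2 (0.86 ± 0.22) on the higher. By limma 0 genes passed, 758 had p under 0.05 (501 higher, 257 lower; median of all genes 0.132), the smallest adjusted p was 0.521, array weights gave 4251 (2943 with the pairs averaged), and without Het saline 1, 3 passed, Npy among them (-2.15, limma adjusted p = 0.000594). For TTK21 on CSP 0 genes passed, 477 had p under 0.05 (302 higher, 175 lower), with Cyb561d2 (1.17 ± 0.24) and Prpsap1 (0.92 ± 0.21) first, array weights gave 1477 (102 with the pairs averaged) and leaving out Het CSP-TTK21 3 gave 1. Of the lists, 14 passed for CSP and 10 for TTK21 on CSP with camera and none with an estimated correlation (lowest adjusted p = 0.301 and 0.554). Of the camera calls 10 for CSP and 6 for TTK21 on CSP were lost without at least 1 library, and 7 and 1 with the length covariate.

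The lists that differed between genotypes and held without each library were choroid plexus, oxidative phosphorylation, interferon response and dentate granule for CSP (camera adjusted p = 8.66e-07, 1.6e-10, 0.000144 and 0.00563). The length covariate ended the oxidative phosphorylation (0.0543) and interferon (0.0908) calls. Choroid plexus had a median of -1.16 in WT and 0.22 in Het, and the interferon list 0.03 and -0.16. For TTK21 on CSP they were myelin, endothelium, heat shock and ependyma (camera adjusted p = 4.14e-09, 7.78e-06, 0.000464 and 0.000483). When adjusted over the list alone Dock10 (0.93 ± 0.26), Isg15 and Xaf1 (-1.76 ± 0.49) passed for CSP and none for TTK21, and the 8 lists had adjusted p = 0.596, 0.466, 0.301, 0.596, 0.606, 0.554, 0.606 and 0.606 with an estimated correlation.

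Log2 fold changes of comparisons were correlated across the 14353 genes, which are not independent replicates. Genotype in saline and TTK21 on CSP in Het, which share no libraries, had r = -0.04 (rho = 0.01, covariance -0.0036), and 84 of 100 relabellings lay as far from 0. Genotype in saline and CSP-TTK21 in Het, which share the 3 Het saline libraries, had r = -0.47 and a covariance of -0.0374, where unchanged groups simulated against the same libraries gave -0.50 and -0.0371. The r was -0.64 without Het saline 1 and -0.61 without Het saline 2. The effects of CSP in the 2 genotypes had r = 0.10 (44 of 100 relabellings as far), which was 0.24 without Het saline 1, -0.07 without Het saline 2, -0.11 without Het CSP 1 and 0.29 without Het CSP 2. The effects of TTK21 on CSP in the 2 genotypes had r = 0.00 (95 of 100 as far). With the description band these last 2 were 0.40 and 0.37.

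Of the 33 lists tested, 25 passed in at least 1 of the 13 comparisons and 8 in none. The 8 and their lowest camera adjusted p, with the median in that comparison, were acetyltransferases, deacetylases and CREB (0.152, -0.18), GABAergic interneurons (0.0501, -0.04), CA2 and CA3 pyramidal cells (0.277, -0.27), microglia (0.135, -0.08), thalamus and habenula (0.0602, 0.03), striatum (0.0953, 0.09), histones (0.421, 0.04) and neurotrophins and growth factors (0.108, -0.21). The circadian clock list passed in both interactions only (camera adjusted p = 0.029 for CSP, median 0.31, and 0.0108 for TTK21 on CSP, median -0.21; adjusted p = 0.732 and 0.606 with an estimated correlation).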

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

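The tests of a strain haplotype, of the length trend, of the loss of a Syngap1 copy, of linked genes weighted by their spread and of labels falling by chance on chromosome 17 were chosen after the result was seen; the other splits of the samples and the tests of fragments, swapped labels, striatal tissue and seizures were written before.

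Genes near Syngap1 differed by genotype. Within 25 Mb of Syngap1 22 of 492 tested genes (4.47%) had p under 0.01 by limma, against 194 of 13860 elsewhere (1.4%; odds ratio 3.3). Of 100 relabellings of genotype within treatment, 3 gave as many there (22 in the real labels, 24 the highest other), but the window was chosen after its genes were seen, and 10 of the 100 had a window somewhere in the genome with as high a share, so chance stays open for the window. With the length slope as a covariate 3 of the 3 called genes stayed past the threshold, which argues against the length trend. A strain haplotype carried with the mutant allele may explain the pattern, but the window ranked 2 of 91 (highest other 5.51%), and the 1 library whose score of 10 linked genes parted from its label (WT CSP 3, 0.14) had 6 of the 10 on the WT side, so a haplotype and an effect of the lost Syngap1 copy cannot be told apart.

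Syngap1 varied widely among libraries of a genotype, from 24.8 to 93.4 TPM in Het. Its TPM followed the length slope (r = 0.89 over 18 libraries, permutation p = 1e-05, the smallest possible), within WT (r = 0.85, permutation p = 0.00371, and 0.64 without 2 libraries) and within Het (r = 0.95, permutation p = 0.00031). The number of fragments correlated with Syngap1 at r = -0.18 (permutation p = 0.482) and with the length slope at r = -0.44 (permutation p = 0.0657; r = -0.18 without 2 libraries), so 18 libraries leave a part for depth open. For swapped labels, the linked score placed 1 library, WT CSP 3, with Het, but its Dynlt1b (54.7 TPM) and Gnptg (90.25 TPM) lay outside the Het range, and with genes weighted by their spread 0 of 18 libraries sided with the other genotype. No library was clearly swapped, but some, such as WT CSP 3 (-0.16) and Het saline 2 (0.14), lay near the middle of that score (-1 at the WT mean, 1 at Het), which keeps it open. A trend such as RNA integrity or library preparation may therefore account for part of the spread in Syngap1, and was not tested beyond length.

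In Het saline 2 and 3 Npy (1534 and 1350 TPM), Penk (291 and 307) and Gfap (497 and 517) were high. Against striatal tissue, 12 other striatal genes had median ratios to the 18 libraries of 1.04 and 0.891, though Drd1 was at 9.58 and 6.93 TPM. Against the length trend, Npy was at 1.49 with it as covariate and 1.47 without. A score of genes that move after seizures was 0.99 and 1.62 in these libraries and -0.82 to 0.31 in the other 16. It correlated with Npy at r = 0.80 (permutation p = 0.00277), but rho was 0.24 (permutation p = 0.325) and r was 0.13 without these 2 libraries. The immediate early gene score fell as Npy rose (r = -0.46, rho = -0.58, permutation p = 0.054 and 0.0125). Fos, Nr4a1 and Npas4 were lower in these 2 than in the other 16, and Bdnf higher. A response like that after seizures may be the source, a hypothesis that rests on 2 libraries.

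The following lists had interaction terms past the threshold by camera with the preset correlation, and none of the 24 did with an estimated one (camera adjusted p, with medians in WT and Het). For CSP against saline they were astrocytes (0.00914; -0.17 and 0.12), choroid plexus (8.66e-07; -1.16 and 0.22), circadian clock (0.029; -0.20 and 0.17), ribosomal proteins (7.35e-05; 0.19 and 0.04), dentate granule (0.00563; -0.22 and 0.27), endothelium (0.0102; -0.18 and 0.22) and glucocorticoid response (0.0494; -0.18 and 0.11). Further lists for CSP were heat shock (0.00657; 0.07 and 0.04), immediate early genes (0.029; -0.22 and 0.08), disability and autism genes (0.000259; -0.29 and 0.06), interferon response (0.000144; 0.03 and -0.16), oxidative phosphorylation (1.6e-10; 0.12 and -0.07), postsynaptic density (0.000972; -0.28 and 0.01) and channels (0.00563; -0.26 and 0.04).

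For TTK21 on CSP the camera adjusted p was 0.03 for astrocytes (0.00 and -0.13), 0.0108 for circadian clock (0.11 and -0.12), 7.78e-06 for endothelium (0.13 and -0.28), 0.000483 for ependyma (-0.23 and 0.40), 0.00025 for glucocorticoid response (0.08 and -0.40), 0.000464 for heat shock (-0.01 and 0.24), 0.03 for inflammation (-0.05 and -0.47), 0.049 for meninges (0.05 and -0.12), 0.0497 for oligodendrocyte precursors (-0.02 and 0.18) and 4.14e-09 for myelin (0.00 and 0.54). For CSP 10 of the 14 calls were lost without at least 1 library, with the highest adjusted p at 0.332 for astrocytes (without Het CSP 1), 0.0725, 0.0561, 0.391 and 0.701 for postsynaptic density, disability and autism genes, channels and ribosomal proteins (without Het CSP 2), and 0.316, 0.14, 0.339, 0.114 and 0.187 for circadian clock, endothelium, glucocorticoid response, heat shock and immediate early genes (without Het CSP 3). For TTK21 on CSP 6 of the 10 were lost, at 0.602 and 0.344 for astrocytes and meninges (without Het CSP 1), 0.724, 0.908 and 0.283 for glucocorticoid response, inflammation and circadian clock (without Het CSP 3) and 0.472 for precursors (without WT CSP-TTK21 2).

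The length covariate ended 7 of the 14 CSP calls, those of ribosomal proteins (0.125), postsynaptic density (0.125), disability and autism genes (0.206), channels (0.391), circadian clock (0.0669), interferon (0.0908) and oxidative phosphorylation (0.0543), and that of precursors for TTK21 on CSP (0.26). Averaging the pairs ended those of glucocorticoid response for CSP (0.053) and of astrocytes (0.0947) and precursors (0.0556) for TTK21 on CSP, and the description number band those of astrocytes (0.0576) and immediate early genes (0.0576) for CSP and of precursors (0.125).

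Genes were counted in the splits at an adjusted p under 0.05 for CSP in Het and for genotype over all treatments, and at an unadjusted p under 0.05 for the other 11 comparisons, where limma called 0 genes. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Splits with as many genes, with the real and the highest other number, were 3 (1049 and 1576) for genotype in saline, 1 (855 and 291) for CSP in WT, 8 (1 and 3423) for CSP in Het, 4 (282 and 594) and 8 (617 and 3864) for TTK21 on CSP in WT and Het, 1 (353 and 303) and 8 (670 and 1825) for CSP-TTK21 in WT and Het, and 1 (621 and 468) for treated Het against saline WT. Splits with as many lists were, in that order, 2 (15 and 16), 1 (12 and 11), 8 (5 and 14), 9 (1 and 7), 7 (9 and 13), 4 (7 and 13), 5 (6 and 13) and 7 (3 and 7). Splits with several times the real number of genes by the same measure, as for CSP in Het and TTK21 on CSP in Het, point to a structure of the libraries other than the groups.

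Of 100 splits, the real one included, 2 gave as many genes as genotype over all treatments (3, highest other 3). Such a count was rare, but another split equalled it. It also needs the 2 close pairs to be separate animals (0 genes passed with each averaged), so chance stays open for that count. As many lists came from 36 splits (11 and 17), so chance cannot be excluded for the lists. Nor can it for TTK21 on CSP over both genotypes (72 splits for genes, 416 and 2939; 30 for lists, 11 and 16), CSP over both genotypes (43, 681 and 5309; 76, 7 and 20), the interaction with TTK21 on CSP (57, 477 and 2840; 30, 10 and 15) or that with CSP (42, 758 and 5309; 15, 14 and 19).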

How the results depend on the processing

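The length covariate, averaging of the close pairs, array weights after averaging and transcript rows were tests chosen after the result was seen; the other alternatives were planned. The cause was not tested for any difference given here. Depth of 3.14 to 9.28 M fragments limits genes of low TPM. Groups of 3 were not tested for outliers.

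Array weights, which spanned 13.8 to 0.163 (84.9 times), moved counts most, and rested on replicate 3 in Het saline and Het CSP. Brackets give counts with pairs averaged too. They called 5646 genes (3123) for genotype in saline, 672 and 8271 (7906) for CSP in WT and Het, and 4510 (624) for TTK21 on CSP in Het. CSP-TTK21 had 3 in WT and 3672 (153) in Het, treated Het 264 and genotype over all treatments 3192 (1218). Over both genotypes TTK21 on CSP had 1784 (70) and CSP 5175 (4007), and their interactions with genotype 1477 (102) and 4251 (2943).

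CSP in Het had 0 genes with no filter, median-ratio scaling, the replicate block, the description number band, the length covariate and transcript rows. For Npy in CSP in Het the limma adjusted p ranged from 3.06e-11 with array weights to 1 with only the groups compared. Fitting only the groups compared called 207 genes for CSP in WT, 1 for CSP-TTK21 in Het and 4 for treated Het against saline WT. Transcript rows called 1 for TTK21 on CSP in Het, 3 for CSP-TTK21 in Het, 2 for treated Het and 1 for TTK21 on CSP over both genotypes. Genotype over all treatments had 5 genes at a mean TPM of at least 5, 9 with the length covariate and 0 with pairs averaged. Syngap1 by genotype was -0.331 with the length covariate and -0.168 with the band. The number of list calls fell from 111 to 0 with an estimated correlation.

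The replicate numbers rise with the order of deposit and were not taken to pair the libraries. Of 45 pairs of libraries with the same number 10 correlated over 0.1 (mean 0.038), and 10 of 18 libraries correlated best with 1 of their own number among those of the other groups. Syngap1 by number was 24.8, 92.6 and 52.9 TPM in Het saline and 26.04, 93.4 and 60.0 TPM in Het CSP, so shared batches of these libraries stay open. With the replicate as a block the exact permutation p of Syngap1 was 0.0598.

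Leaving out 1 library gave 0 to 11 genes for genotype in saline (11 without Het saline 1), 0 to 14 for CSP in Het (14 without Het saline 1; 0 without Het saline 2 or 3 or Het CSP 2 or 3), 0 to 3 for TTK21 on CSP in Het (3 without Het CSP-TTK21 3), 0 to 17 for CSP-TTK21 in Het (17 without Het saline 1, 1 without Het CSP-TTK21 3), 0 to 1 for treated Het (1 without Het CSP-TTK21 3) and 2 to 11 for genotype over all treatments (7 and 11 without Het CSP 1 and 2). It gave 0 to 3 for TTK21 on CSP over both genotypes (3 without Het CSP-TTK21 3), 0 to 2 for CSP over both (2 without Het saline 1), 0 to 1 for the interaction with TTK21 on CSP (1 without Het CSP-TTK21 3), 0 to 3 for that with CSP (3 without Het saline 1), and 97 to 130 list calls. Syngap1 by genotype ran from -0.575 (Het saline 2) and -0.563 (Het CSP 2) to -0.262 (Het CSP 1). The correlation of CSP in WT with CSP in Het ran from -0.11 (Het CSP 1) to 0.29 (Het CSP 2), with -0.07 without Het saline 2 and 0.24 without Het saline 1, and was 0.40 with the band. That of TTK21 on CSP in the 2 genotypes was 0.37 with the band, and genotype in saline with CSP-TTK21 in Het ran from -0.64 (Het saline 1; -0.61 without Het saline 2) to -0.38 (Het CSP-TTK21 2).

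Directions of lists reversed as follows, with camera adjusted p. With the band these were astrocytes for CSP in WT (0.80), myelin (0.29) and glucocorticoid response (0.575) for TTK21 on CSP over both genotypes, and myelin for CSP over both (0.00281). With the length covariate they were ribosomal proteins for CSP in WT (0.609) and for the interaction with CSP (0.125), and at a mean TPM of at least 5 meninges for the interaction with TTK21 on CSP (0.929). Without Het CSP 2 they were oxidative phosphorylation for CSP in Het (0.0502; range without 1 library 1.15e-11 to 0.936) and ribosomal proteins for the interaction with CSP (0.701; 3e-17 to 0.701, and reversed at 0.66 without Het saline 1). Without Het CSP 3 they were glucocorticoid response for TTK21 on CSP in Het (0.918; 8.98e-08 to 0.918), over both genotypes (0.45; 5.11e-05 to 0.45) and for the interaction with CSP (0.339; 0.000298 to 0.339), and inflammation for the interaction with TTK21 on CSP (0.908; 3.97e-06 to 0.908).

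Opalin for TTK21 on CSP over both genotypes was -0.14 with the band. Syngap1, called in none of these, reversed to 0.11 for CSP in WT, -0.19 for TTK21 on CSP in WT, 0.08 for CSP over both genotypes and -0.06 for the interaction with CSP with the length covariate. With the band it was -0.15 for CSP in Het, 0.24 for TTK21 on CSP in Het, 0.09 for CSP-TTK21 in Het and 0.27 for TTK21 on CSP over both genotypes. Without 1 library it ran from -0.40 (Het saline 1) to 0.58 for CSP in Het, with -0.32 and 0.00 without Het CSP 2 and 3, from -0.03 (WT CSP 3) to 0.14 for TTK21 on CSP in WT, and from -0.75 to 0.15 (Het CSP 2) for TTK21 on CSP in Het. It ran from -0.65 to 0.28 (Het saline 2; 0.04 without Het CSP-TTK21 3) for CSP-TTK21 in Het and from -0.35 to 0.10 (Het CSP 2; 0.01 without Het CSP-TTK21 3) for TTK21 on CSP over both. For CSP over both it ran from -0.44 to 0.05 (Het CSP 1; 0.03 without Het saline 2), and for the interaction with TTK21 on CSP from -0.81 to 0.09 (Het CSP 2).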

Other observations

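The genes and libraries described here were picked after the values were seen, and no tests were added.

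Growth hormone (Gh), a pituitary transcript, was at 7.64 and 6.41 TPM in WT saline 1 and 2, a close pair. It was at 0.33 TPM in WT CSP-TTK21 1 and at 0 in the other libraries. The ribosomal precursor Rn45s ran from 1104 TPM in WT CSP-TTK21 3 to 12329 TPM in Het CSP-TTK21 3.

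Of 11 genes that move after seizures some lay outside the range of the other 16 libraries in both Het saline 2 and 3. Scg2 was at 330 and 280 TPM, Bdnf at 35.3 and 42.65, the astrocyte serpin Serpina3n at 227 and 194 and Gal at 7.03 and 11.9. Vgf was at 301 and 300 TPM, Cd44 at 3.18 and 3.04 and Calb1, which falls, at 92.5 and 77.5. In Het saline 3 alone, Vim was above that range at 71.9 TPM (55.3 in Het saline 2) and Pdyn, which falls, below it at 4.04 (6.93). Crh (2.98 and 2.95 TPM) lay within the range of the other 16 (1.41 to 6.04), and so did Timp1 (0 and 0.77, 0 to 3.64).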
